A study of Homo sapiens with 17 samples.

How the data were processed

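Bulk RNA was measured in 11 libraries of day 35 cerebral organoids of the H9 human embryonic stem cell line (3 ethanol control, 3 DHT at 30 nM, 3 testosterone at 100 nM, 2 estradiol at 100 nM), each from RNA pooled over organoids of 1 treatment, and single-cell RNA in 6 droplet libraries (2 control, 2 DHT at 30 nM, 2 estradiol at 100 nM). Treatment ran from day 17 to day 35. For bulk, the authors quantified poly(A) RNA with Salmon 0.14.1 on GRCh38/hg38; the deposited bulk values are TPM per gene. The table held 33644 gene identifiers, 33483 with a symbol, of which 18522 were protein-coding and 14688 were pseudogenes. Of the protein-coding genes with a single annotated transcript it held 60.2%, against 98.1% of those with more, so genes such as SOX2 and NEUROD6 were not analysed in bulk, and the listed genes of each library sum to 805550 to 829058 TPM. For single cells, the authors used bcl2fastq, Cell Ranger 3.1.0 with STAR on GRCh38 and Seurat 3, and the deposited single-cell values are UMI counts per gene and cell, with no normalization. In the deposited cells the lowest UMI total per cell was 498 to 512 in each library and the highest mitochondrial share 9.67% to 9.99%, so cells outside those bounds had been left out before deposit. Genes counted in fewer than 3 cells were nearly absent in some libraries, so a single-cell 0 is no measured limit and no fold is given for a gene at 0 in a library group. DESeq2 1.28 is also named in the labels; its output was not used here. Positions and gene types were taken from a GENCODE annotation of GRCh38, which may differ in release from that of the authors.

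Groups were taken from the labels. The tags 1706, 1805 and 0802 in the bulk names were treated as batches. After group means were removed, 10 of 15 pairs of libraries with the same tag were correlated above 0.1. Pairs with different tags were not compared, so these correlations do not show that the tags are batches. The main test used no block, and a blocked value stands beside a result wherever it changes a call or moves a count by more than 1.5 times. The numbers 1 and 2 of the single-cell libraries were not taken to pair them, since over tested genes the difference between the numbers correlated at 0.204 in control and DHT but at -0.06 in control and estradiol and 0.04 in DHT and estradiol. Bulk genes with at least 1 TPM in at least 2 libraries were kept (14275 genes), values were log2 of TPM plus a pseudocount of 1, and limma 3.58.1 (trended variance) in R 4.3.3 fitted all 11 libraries at once. Calls were made at a Benjamini-Hochberg adjusted p under 0.05. The 28 gene lists with enough measured members of 30 fixed lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists, in 6 bulk and 3 single-cell comparisons. They covered cell types (radial glia, outer radial glia, intermediate progenitors, excitatory, inhibitory and pan-neuronal genes, Cajal-Retzius cells, choroid plexus, cortical hem, mesenchyme, midbrain and hindbrain, retina, astroglia, microglia and endothelium, muscle, pluripotency), the cell cycle (S phase, G2 and M phase), and pathways (androgen and estrogen response, steroid receptors and enzymes, histone deacetylases, mTOR, cholesterol synthesis, hypoxia and glycolysis, unfolded protein response, immediate early genes, Notch, Wnt, mitochondrially encoded genes). The lists for pluripotency and for microglia and endothelium had too few measured members in bulk, as did those for pluripotency and muscle in single cells. The correlation of the DHT and testosterone fold changes was compared with 100 simulated sets of libraries without a treatment effect.

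Single cells with at least 200 detected genes were normalised and clustered with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.8; Python 3.11.15, anndata 0.12.19, igraph 0.11.9). A cluster could take the name of a type where at least 3 of the type's markers, and at least 30% of them (50% for dividing cells), passed. A marker passed when it was 1.5 times higher in the cluster than outside it and detected in 5% of its cells. Dividing cells came first, and otherwise the type with the highest share of passing markers was taken. Clusters that came out as intermediate progenitors or Cajal-Retzius cells were named excitatory neuron-like where at least 50% of the pan-neuronal markers passed. A cluster with no marker of its type or a related type among its 10 leading genes was left unnamed, a step chosen after the clusters were seen. Doublet scoring with Scrublet called 97.4% of the cells of DHT 1 and under 0.5% of those of each other library, so it was taken to have failed and no doublets were removed. UMIs were summed per library, over all cells (12703 genes tested) and within classes with at least 20 cells in every library (10028 genes in radial glia-like, 6672 in dividing-like and 7732 in excitatory neuron-like cells), and tested with the quasi-likelihood test of edgeR 4.0.16 after TMM scaling and filterByExpr; DESeq2 1.42.0 was the alternative. Standard errors of edgeR fold changes were worked back from the fold change and its p. Class shares were compared by exact two-sided permutation tests, in which 2 against 2 libraries cannot go below 0.333. Intervals of shares are exact Clopper-Pearson 95% intervals and cover counting error only.

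Genes were named by a rule fixed before the data were examined: up to 10 per direction past the threshold with 1 sign in every batch and a mean of at least 1 TPM or 10 CPM; where fewer than 5 passed, the 5 with the smallest p, named as not passing; the 4 members of a described list with the smallest p; and a fixed set (among them ESR1, ESR2, PGR, SRD5A1, CYP19A1, FKBP5, KLK3, HDAC2, HDAC3, MTOR, SOX2, PAX6, HOPX, EOMES, TBR1, NEUROD6, DLX2, GAD2, MKI67, TTR). Some genes that this rule picked are not reported here. Comparisons, lists, tests and most alternatives were also fixed before the data were examined. On simulated data with 200 changed genes, the bulk test recovered 25.4% to 52.2% of log2 changes of 1, 62.7% to 86.6% of changes of 2 and 83.3% to 100% of changes of 3. The single-cell tests recovered 2.99% to 25.4%, 61.2% to 86.6% and 84.8% to 97.0%. False calls numbered 1 to 12 per comparison in bulk and 3 to 15 in single cells. These simulated libraries were drawn without batches. The alternatives were a pseudocount of 0.1 TPM, no filter or a mean of at least 5 TPM, rescaling by median ratios, a replicate block, fits of only the groups compared, leaving out each library, other cell filters and cluster resolutions (0.4 and 1.5), centring by library before clustering, and DESeq2 scaling or testing.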

Results

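Transcript levels were measured in cerebral organoids grown from H9, an established human embryonic stem cell line, and treated with sex steroids from day 17 to day 35. The bulk set held 11 libraries, each from RNA pooled over organoids of 1 treatment: 3 of ethanol control, 3 of dihydrotestosterone (DHT, 30 nM), 3 of testosterone (100 nM) and 2 of estradiol (100 nM). Their names carried the tags 1706, 1805 and 0802, treated here as batches; 0802 had no estradiol library. The bulk table gave TPM, a length-corrected share of transcripts, for 33644 gene identifiers, of which 3060 were at 0 in all 11 libraries. The listed genes summed to 805550 to 829058 TPM per library, and 12497 to 13039 genes reached 1 TPM; read totals are not part of that table, so the counting depth of the bulk values is unknown. The single-cell set held 6899 cells and 26838195 UMIs over 17583 genes, from 2 libraries each of control, DHT (30 nM) and estradiol (100 nM). Control 1 held 1532 cells and 10980321 UMIs, control 2 held 1404 cells and 4339834 UMIs, DHT 1 held 543 cells and 2005867 UMIs, and DHT 2 held 1380 cells and 3347752 UMIs. Estradiol 1 held 1173 cells and 2099105 UMIs, and estradiol 2 held 867 cells and 4065316 UMIs. Median UMIs per cell ran from 1129 in estradiol 1 to 4324.5 in control 1. Coordinates are those of GRCh38.

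The comparison of DHT with control asked what an androgen that aromatase cannot turn into an estrogen does to the transcripts of developing cortical tissue. All 13 mitochondrially encoded genes, which code for subunits of the respiratory chain and the ATP synthase, were lower, with a median log2 fold change of -0.71 (camera, adjusted p = 4.8e-13; 0.474 with an estimated correlation). MT-ND4L gave -0.91 (SE 0.24) and MT-CO2 gave -0.67 (SE 0.18), both lower in 3 of 3 batches. Genes of S phase were higher as a group, 16 of 20 with a median of 0.24 (adjusted p = 1.7e-05; 0.474 with an estimated correlation); MCM4, a subunit of the replicative helicase, had 238 ± 19.4 TPM in control and 281 ± 18.3 in DHT (SD, n = 3; log2 0.24, SE 0.11) and did not pass alone. All 9 measured genes of the cortical hem, the signalling centre at the edge of the cortex, were lower (median -0.65, adjusted p = 0.0134; 0.657 with an estimated correlation; RSPO3 -0.73, SE 0.30; WNT5A -0.90, SE 0.49). Genes of cholesterol synthesis were called higher although 10 lay above and 10 below 0, with a median of 0.02 (adjusted p = 0.0397; 0.587 with an estimated correlation; ACAT2 0.34, SE 0.12; FDFT1 0.61, SE 0.28). Of the choroid plexus markers, another tissue type, 12 of 12 lay below control, with a median of -0.56 (camera, adjusted p = 0.113). The batches were not alike in this. Against the control of the same batch their median was -0.83 in DHT 1706 and -1.39 in DHT 1805, but 0.78 in DHT 0802.

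None of these 4 calls of camera held with an estimated correlation. Adjusted over the list alone, 12 of the 13 mitochondrially encoded genes were lower; adjusted over all genes, none was. The median of the 13 genes was below 0 in each batch, from -1.05 to -0.02; that of the hem genes was below 0 in 2 of 3 batches, from -1.56 to 0.46. In principal components DHT 1805 stood apart from the other libraries (-55.3 on the second, against -13.0 to 20.6), and ribosomal protein genes made up 22.3% of its listed TPM against 16.3% in its control; without it S phase lay at 0.20 and was still called. The cholesterol call was lost without DHT 1706, control 1805 or DHT 1805. The hem call was lost without the DHT library of batch 1706 (adjusted p = 0.475), the control library of 1805 (0.230) or the DHT library of 1805 (0.0758). With the batch as a replicate block, camera called 6 lists, among them choroid plexus (adjusted p = 0.0276) and Cajal-Retzius cells (adjusted p = 0.0159), early neurons of the cortical surface.

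Gene by gene, limma called 2 of 14275 genes between DHT and control, both pseudogenes listed at 0 in every library of 1 side. SPTLC1P1, a transcribed processed pseudogene at chromosome 10, 31360955 to 31361215, had 18.6, 5.91 and 38.9 TPM in the DHT libraries of batches 1706, 1805 and 0802 and was listed at 0 in the other 8 libraries (adjusted p = 0.0483). The processed pseudogene ENSG00000268593 at chromosome 19, 55707550 to 55707855, had 5.21, 2.88 and 2.80 TPM in the control libraries and was listed at 0 elsewhere (adjusted p = 0.0483); it has no symbol and was chosen after its values were seen. Next by p, and not past the threshold, came UNC13D (chromosome 17, 75827225 to 75844717), which takes part in the release of cytotoxic granules, with 6.87 ± 0.25 TPM in control and 1.10 ± 0.68 in DHT (SD, n = 3; log2 -1.96, SE 0.28, adjusted p = 0.165). RBPMS (log2 -1.58, SE 0.29) and the myosin gene MYO1D (-1.63, SE 0.31) were lower in 3 of 3 batches with an adjusted p of 0.723. A total of 901 genes had an unadjusted p under 0.05; with the batch as a replicate block 1388 did, and 0 passed limma's adjustment. Without the DHT library of batch 0802, limma called 20 genes.

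Genes tied to the question of the series did not pass in this comparison. HDAC2, a histone deacetylase, had 238 ± 14.8 TPM in control and 267 ± 14.9 in DHT (SD, n = 3; log2 0.17, SE 0.11), and HDAC3 gave 0.18 (SE 0.12), both above control in 3 of 3 batches. SRD5A1, the enzyme that makes DHT from testosterone, gave 0.39 (SE 0.22; 5.40 ± 0.36 against 7.45 ± 1.42 TPM), and MTOR gave -0.16 (SE 0.17). The radial glia gene PAX6 gave 0.29 (SE 0.24), the intermediate progenitor gene EOMES 0.20 (SE 0.28) and the deep-layer neuron gene TBR1 -0.04 (SE 0.42). HOPX gave 0.22, FKBP5 0.01, GAD2 -0.36, ESR2 0.12, MKI67 -0.21 and TTR -0.66, and the smallest adjusted p among all these named genes was 0.807. The intermediate progenitor list lay at a median of 0.20 with 6 of 7 genes above 0 (adjusted p = 0.147), the radial glia list at 0.16 (0.276) and the outer radial glia list at -0.60 with 8 of 10 genes below 0 (0.0657). The androgen response list lay at -0.23 (adjusted p = 0.265). ESR1, PGR, CYP19A1 and KLK3 averaged at most 0.157 TPM in any group. SOX2 and NEUROD6 were missing from the bulk values, and DLX2 was listed there but did not pass the filter, so none of them was tested in bulk.

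Testosterone, which cells can convert to DHT or to estradiol, was compared with control in the same way. The 13 mitochondrially encoded genes were again all lower, with a median log2 fold change of -0.54 (adjusted p = 2.2e-18; 0.233 with an estimated correlation; MT-ATP8 -0.99, SE 0.26; MT-CO2 -0.51, SE 0.18). Genes of steroid receptors and steroid enzymes were higher as a group, 10 of 11 with a median of 0.22 (adjusted p = 0.0269; 0.233 with an estimated correlation; call lost without testosterone 1706, control 1805 or control 0802): NR3C2, the mineralocorticoid receptor, gave 0.64 (SE 0.29), SRD5A1 0.34 (SE 0.22) and the estrogen receptor gene ESR2 0.87 (SE 0.41). The pan-neuronal list had 13 of 13 genes above 0 (median 0.21) without passing (adjusted p = 0.125), and S phase lay at 0.16 (adjusted p = 0.0635). Adjusted over the list alone, 10 of the 13 mitochondrially encoded genes were lower. The choroid plexus markers had 9 of 12 genes below 0, with a median of -0.16 (adjusted p = 0.455).

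Single genes did not pass between testosterone and control: limma called 0 of 14275 genes, with 389 at an unadjusted p under 0.05; with the batch as a replicate block it called 0 and had 683. The smallest adjusted p was 0.0557, for the pseudogene ENSG00000268593 described above. The genes named next had an adjusted p of 1, and all kept their sign in 3 of 3 batches. LNP1 (log2 1.62, SE 0.34), the synaptic glutamate receptor gene GRM7 (1.89, SE 0.43) and CSMD1 (1.25, SE 0.28) were above control. LMAN1, a cargo receptor of the early secretory pathway, was below it (-1.49, SE 0.33; 5.07 ± 2.42 against 1.07 ± 0.50 TPM), as was CC2D1B (-1.11, SE 0.25; 87.2 ± 17.4 against 40.4 ± 12.7 TPM; SD, n = 3). HDAC2 gave 0.15 (SE 0.11), HDAC3 0.14, PAX6 0.21, EOMES 0.13, TBR1 0.20, FKBP5 0.16, HOPX 0.17, GAD2 -0.22, MTOR -0.12, MKI67 -0.09 and TTR -0.50.

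The pooled comparison of both androgens with control covered 6 treated and 3 control libraries at unequal doses. Mitochondrially encoded transcripts made up 8.19% ± 1.68 of the listed TPM in control (SD, n = 3), 4.98% ± 1.09 in DHT (n = 3), 5.31% ± 0.48 in testosterone (n = 3) and 7.60% ± 1.38 in estradiol (n = 2). The share of each of the 6 androgen libraries (5.15% ± 0.78) was below that of each control and each estradiol library. An exact two-sided permutation test gave p = 0.0119 against control, the smallest its 84 splits allow (adjusted p = 0.0952 over 8 comparisons), and exact p = 0.0357 against estradiol (adjusted 0.143). Taken singly, DHT and testosterone against control both gave an exact p of 0.1, the smallest that 3 against 3 libraries allow. Within batches, the log2 difference of the mean androgen share from control was -0.11 in 1706, -0.97 in 1805 and -0.90 in 0802. The permutation test shuffled libraries across batches. DHT and testosterone libraries of the same batch were correlated after group means were removed (0.414 in 1706, 0.110 in 1805 and 0.378 in 0802). The 6 androgen libraries were thus not independent units, which the exact p values leave out of account. This test was chosen after the values were seen.

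**Figure D1:**
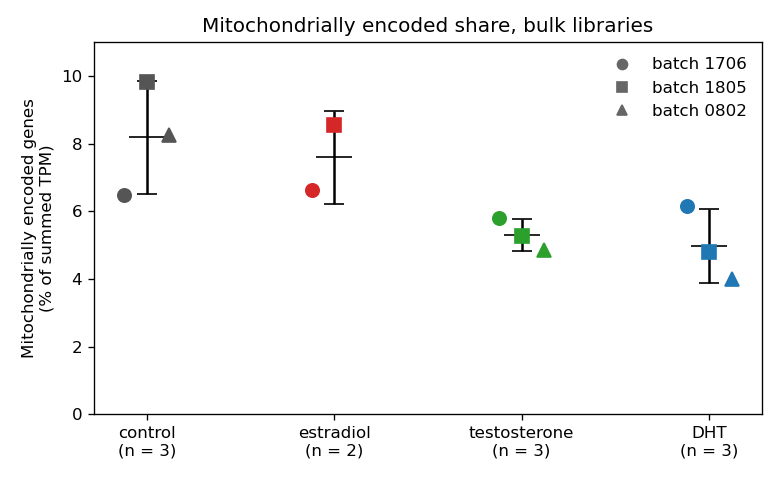
Percent of the listed TPM in the 13 mitochondrially encoded genes (vertical axis) by treatment (horizontal axis); points are bulk libraries by batch, lines are group means and bars are 1 SD. Control libraries lie between 6.48% and 9.83%, and the 6 androgen libraries between 3.99% and 6.16%.

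Over the 28 lists, camera called 3 between androgens and control. The mitochondrially encoded list had a median of -0.64 (adjusted p = 3.3e-19; all 13 genes lower adjusted over the list alone; adjusted p = 0.322 with an estimated correlation). S phase had a median of 0.18 with 17 of 20 genes above 0 (adjusted p = 1.2e-04; adjusted p = 0.322 with an estimated correlation), among them MCM4 (0.27, SE 0.10), UNG (0.42, SE 0.20), FEN1 (0.33, SE 0.16) and MCM5 (0.26, SE 0.14). Cholesterol synthesis had a median of 0.12 with 16 of 20 above 0 (adjusted p = 0.0277; adjusted p = 0.539 with an estimated correlation). The S phase call was lost without control 1805, and the cholesterol call without that library or any androgen library of 1706 or 1805. Choroid plexus markers lay below 0 in 11 of 12 (median -0.39, adjusted p = 0.177), and hem markers in 9 of 9 (median -0.24, adjusted p = 0.198). Intermediate progenitor genes lay above 0 in 6 of 7 (median 0.26, adjusted p = 0.172). Excitatory cortical neuron genes split evenly, 8 above and 8 below 0 (median 0.02, adjusted p = 0.416). With the batch as a replicate block, camera also called steroid receptors and steroid enzymes (9 of 11 above 0, adjusted p = 0.0690 without and 0.0236 with the block).

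By single genes, limma called 1 gene between androgens and control, the pseudogene ENSG00000268593 (adjusted p = 0.0146), chosen after its values were seen. UNC13D gave -1.47 (SE 0.24, adjusted p = 0.805). CC2D1B (-1.14, SE 0.21), LMAN1 (-1.46, SE 0.28) and EIF2B3, a subunit of a translation initiation factor (0.63, SE 0.13), had an adjusted p of 0.999 and the same sign in 3 of 3 batches. There were 561 genes at an unadjusted p under 0.05; with the batch as a replicate block there were 938, and limma called 0.

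Estradiol was compared with control to set the androgen effects against an estrogen. Limma called 1 gene, the unprocessed pseudogene ENSG00000265630 at chromosome 10, 47563604 to 47569697, with 7.06 and 3.86 TPM in the estradiol libraries of batches 1706 and 1805 and listed at 0 in the other 9 (adjusted p = 0.0204); it was chosen after its values were seen. DMRT3, a transcription factor gene, was listed at 0 in both estradiol libraries and had 2.09, 5.12 and 4.73 TPM in the control libraries of batches 1706, 1805 and 0802 (adjusted p = 1). GIPC2 was listed at 0 in all 3 control libraries and had 1.79 and 1.22 TPM in estradiol, and SERF1B, a gene with a near-identical copy whose reads cannot be placed with certainty, gave 1.79 (SE 0.40); the pseudogenes RNA5SP440 and LSM3P3 came with them, and all had an adjusted p of 1. PAX6 gave 0.44 (SE 0.27), TBR1 0.52 (SE 0.47), EOMES 0.19, HDAC2 -0.05, HDAC3 0.18, SRD5A1 0.14 and MTOR 0.17, none of which passed. Camera called 0 of 28 lists; the smallest adjusted p was 0.339, for S phase, and 0.973 with an estimated correlation. A total of 265 genes had an unadjusted p under 0.05; with the batch as a replicate block 321 did, and limma called 0.

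The compounds were also set against each other, with the limit that DHT was given at 30 nM and testosterone and estradiol at 100 nM. Between DHT and testosterone, all 9 hem genes were lower in DHT (median -0.81; RSPO3 -1.05, SE 0.30; MSX1 -0.95, SE 0.39; adjusted p = 0.0063; adjusted p = 0.871 with an estimated correlation). Their median was below 0 in 2 of 3 batches, from -1.37 to 0.03, and the call was lost without DHT 1706, testosterone 1805 or testosterone 0802. Choroid plexus markers lay below 0 in 11 of 12 (median -0.41, adjusted p = 0.431). The outer radial glia list lay at -0.68 (adjusted p = 0.0543), and the mitochondrially encoded list differed by -0.16 (adjusted p = 0.680). KLHL13, a substrate adaptor of a ubiquitin ligase at chromosome X, 117897813 to 118117340, had 6.58 ± 1.54 TPM in DHT and 19.1 ± 1.97 in testosterone (SD, n = 3; log2 -1.42, SE 0.22, adjusted p = 0.397). SPTLC1P1 (adjusted p = 0.0965), GIPC2, SRP72 (1.36, SE 0.28) and CLCC1 (-0.62, SE 0.13; adjusted p = 0.814) did not pass either. Limma called 0 genes, with 812 at an unadjusted p under 0.05; with the batch as a replicate block it called 0 with 1142. Without DHT 0802, and with no block, limma called 20. Blocked, camera called 5 lists in place of 1: the hem, and Cajal-Retzius cells, midbrain and hindbrain, S phase and estrogen response (adjusted p = 0.0496 for these 4).

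Against estradiol, both androgens showed the pseudogene ENSG00000265630 as the 1 gene called by limma (adjusted p = 0.0204 for each, and 0.00708 for the pooled androgens). The mitochondrially encoded genes were lower in the pooled androgens than in estradiol, 13 of 13 with a median of -0.63 (adjusted p = 5.6e-14; adjusted p = 0.828 with an estimated correlation), and 11 of them were lower adjusted over the list alone; choroid plexus markers lay below 0 in 11 of 12 (median -0.36, adjusted p = 0.416). KLHL13 was lower in DHT than in estradiol without passing (log2 -1.41, SE 0.24, adjusted p = 0.706), as were UNC13D (-1.51, SE 0.31) and B3GNTL1 (-1.23, SE 0.25), both with an adjusted p of 0.935. Testosterone against estradiol gave BCAP29 at 1.15 (SE 0.24) and GFPT2, an enzyme of hexosamine synthesis, at 1.05 (SE 0.25), both with an adjusted p of 1. The pooled androgens gave BCAP29 at 0.92 (SE 0.22), SNX7 at -1.33 (SE 0.32) and the neurotrophin gene NTF4 at -1.29 (SE 0.32), all with an adjusted p of 0.993. The median log2 fold change of all genes was -0.12 between DHT and estradiol, -0.0969 between DHT and testosterone and -0.0847 between DHT and control, so single values and counts of genes below 0 in these comparisons include that shift. Unadjusted p under 0.05 was reached by 582 genes for DHT, 272 for testosterone and 322 for the pooled androgens against estradiol; with the batch as a replicate block these were 789, 316 and 410, limma called 0 in each, and camera called 6 lists in place of 1 for the pooled androgens: the mitochondrially encoded list, choroid plexus (adjusted p = 0.0026), mesenchyme and neural crest (6.9e-04), hypoxia and glycolysis (6.6e-05), and the hem and steroid lists (0.0486 for both).

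Whether DHT and testosterone moved the same genes was read from the correlation of their fold changes against the shared control, across genes, which are not independent replicates. Pearson's r was 0.435 over 14275 genes, Spearman's rho was 0.420, and 64.01% of genes had the same sign. Libraries simulated without any treatment effect gave a mean r of 0.498 (range 0.466 to 0.528 in 100 simulations), since both differences hold the same control libraries; their mean rho was 0.457 and their mean share of same signs 66.6%. The measured correlation was below that range, so the simulated libraries, drawn without batches, did not describe the measured ones. Without batch 1805 or 0802 r was 0.508, and neither a shared response beyond the shared control nor its absence can be read from this value.

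In the single-cell libraries, clusters were named from fixed markers. The 484 cells of the choroid plexus or hem-like cluster were led by HTR2C and TTR, the thyroid hormone carrier of the choroid plexus. Radial glia-like clusters were led by SLC1A3, HES5 and FABP7, dividing-like clusters by CENPF, TOP2A and UBE2C, and excitatory neuron-like clusters by STMN2 and NEUROD6. A pair of clusters, of 1300 and 747 cells, could not be named. The first was led by PCP4, CRABP2 and FTL and the second by ribosomal protein genes. The first had a median of 984.5 UMIs per cell, a median mitochondrial share of 0% and 5 markers of stressed cells raised. Radial glia-like cells made up 32.1% ± 0.71 of DHT, 37.2% ± 6.3 of control and 33.7% ± 6.9 of estradiol cells (SD, n = 2). Excitatory neuron-like cells made up 15.4% ± 2.3, 13.5% ± 1.8 and 22.3% ± 13.4 in the same order, and dividing-like cells 11.3% ± 2.7, 10.5% ± 0.74 and 15.6% ± 2.9. Cells of the unnamed clusters made up 36.5% ± 2.5, 26.3% ± 17.2 and 27.3% ± 21.5. Choroid plexus or hem-like cells made up 4.61% ± 1.8, 12.6% ± 9.8 and 1.19% ± 1.7; estradiol 2 held 0 of them in 867 cells, with an exact Clopper-Pearson 95% interval up to 0.425%. The exact two-sided permutation p of every class and comparison was at least 0.333, the smallest that 2 against 2 libraries allow, and the adjusted p was 1 over 15 tests. Cells with a mitochondrial share under 0.5% made up 14.4% of control 1, 57.5% of control 2, 57.8% of DHT 1, 51.8% of DHT 2, 76.0% of estradiol 1 and 21.9% of estradiol 2.

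**Figure D2:**
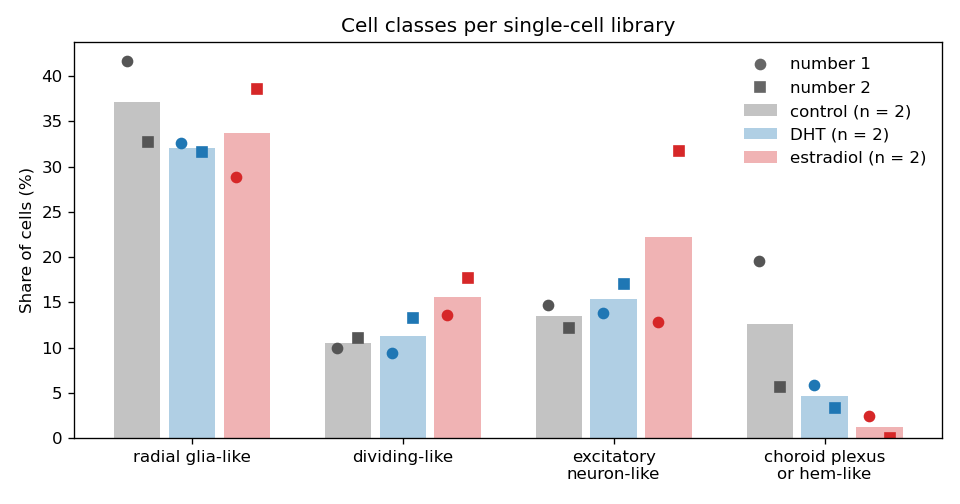
Percent of cells (vertical axis) in each class, by treatment; bars are means of 2 libraries and points are the libraries. The neuron-like share averages 15.4% in DHT, 13.5% in control and 22.3% in estradiol, where the 2 libraries lie far apart.

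DHT was compared with control on UMI sums of whole libraries, where cell shares and expression count together. The tubulin gene TUBB3, made mainly by neurons, had 3.64 and 8.76 CPM, the gene's UMIs scaled to the UMIs of its library, in the control libraries and 15.0 and 18.8 in DHT (log2 1.59, SE 0.56), and the metallothionein gene MT1X gave 1.31 (SE 0.46); neither passed (adjusted p = 1.00). AP1G2 gave 1.38 (SE 0.46), and SPHKAP and ABCA4 were at 0 in both DHT libraries. HDAC2 gave 0.04 (SE 0.26), SRD5A1 0.30, MTOR -0.05, PAX6 0.23, SOX2 0.06, EOMES -0.30, TBR1 0.12, NEUROD6 0.12 and MKI67 -0.57. As groups, S phase genes were higher (median 0.24, 18 of 20), as were cholesterol synthesis (0.15, 19 of 21) and immediate early genes (0.35, 9 of 10), each with an adjusted p of 0.0152 (0.915 with an estimated correlation). So were 4 of 4 midbrain and hindbrain genes (adjusted p = 2.5e-04, and 0.915 with an estimated correlation). The patterning gene HOXB2 had 1.09 and 2.77 CPM in control against 15.0 and 20.6 in DHT. That list held 14 genes, of which 9 were in the single-cell values and 4 passed the count filter. These 4 lay above control in estradiol too, without passing (median 1.02, camera adjusted p = 0.505). Outside the choroid plexus or hem-like cluster, a setting chosen after the data were seen, S phase lay at 0.08 (adjusted p = 0.636) and cholesterol synthesis at 0.0031 (0.491), and neither passed. Choroid plexus markers lay below 0 in 10 of 11 (adjusted p = 0.212; 0.0159 with the library number as a replicate block), and mitochondrially encoded genes in 11 of 13 (median -0.48, adjusted p = 0.133). EdgeR called 0 genes, with 177 at an unadjusted p under 0.05, and DESeq2 called 0; with the library number as a replicate block edgeR called 0, and camera called 6 lists, with choroid plexus and retina and eye (2 of 3 below 0, adjusted p = 0.0942 without and 0.0117 with the block) as the added ones.

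Within classes, no gene passed between DHT and control, and the smallest p values stood in excitatory neuron-like cells. RELN, the secreted guide of cortical layering, had 148 and 31.0 CPM in control neurons and was at 0 in both DHT libraries (adjusted p = 0.115), and the calcium-binding gene CALB2 had 180 ± 55.0 against 33.4 ± 12.99 CPM (SD, n = 2; log2 -2.22, SE 0.54, adjusted p = 0.143). IGFBP5 gave -2.76 (SE 0.73, adjusted p = 0.230), SPHKAP was at 0 in DHT, and EMC10 was high in DHT 1 alone (2548 CPM, against 64.7 in DHT 2). NEUROD6 had 460 ± 7.79 against 309 ± 80.6 CPM, TBR1 164 ± 1.76 against 114 ± 10.5 and HDAC2 328 ± 20.8 against 281 ± 7.04. The radial glia genes SOX2 (41.3 ± 6.42 against 98.8 ± 66.1 CPM) and PAX6 (63.5 ± 2.24 against 110 ± 50.5) lay the other way in the same cells, mostly through DHT 1 (146 CPM for both). Other cells in this class are thus not ruled out, and none of these 5 genes passed. The naming rule could also place Cajal-Retzius cells in this class, and their share in it was not measured. Lower RELN and CALB2 are thus not told apart from a different share of such cells. In radial glia-like cells, the growth factor gene PTN had 182 ± 52.3 CPM in control and 522 ± 30.3 in DHT (log2 1.47, SE 0.39, adjusted p = 0.801); SNHG25 (2.05, SE 0.53), ZIC1 (2.32, SE 0.67) and MGST1 had the same adjusted p. The radial glia-like class joined clusters with medians of 2467, 7586 and 923 UMIs per cell. They held 195, 357 and 86 cells of control 1 and 110, 64 and 285 of control 2. Of DHT 1 they held 35, 36 and 106 cells, and of DHT 2 they held 137, 88 and 211. In dividing-like cells FAM89A gave -2.69 (SE 0.69, adjusted p = 0.625), followed by FGFBP3, RPL36A, HNRNPH1 and SNHG25. Choroid plexus transcripts lay unevenly in these cells: TTR in neuron-like cells had 1915 and 594 CPM in control and 296 and 156 in DHT. EdgeR called 0 genes in the 3 classes, with 1059 at an unadjusted p under 0.05, and DESeq2 called 0; with 1 library left out edgeR called 9 to 18.

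Estradiol was compared with control in the same cells. Choroid plexus markers were lower in whole libraries, 11 of 11 (adjusted p = 9.7e-14; 0.341 with an estimated correlation), as were hem markers, 10 of 10 (median -1.46, adjusted p = 9.5e-07; 0.341 with an estimated correlation). None of the 14 lists called here passed with an estimated correlation, where the smallest adjusted p was 0.341. Intermediate progenitor genes (median 0.64, 12 of 15, adjusted p = 3.2e-08), excitatory cortical neuron genes (0.59, 15 of 18, 5.8e-05) and pan-neuronal genes (0.64, 11 of 14, 4.4e-05) were higher, with S phase (0.51, 19 of 20, 4.1e-08) and G2 and M phase (0.31, 22 of 22, 0.00162). Genes of Cajal-Retzius cells (6 of 8) and the unfolded protein response (16 of 18) were lower too. So were mesenchyme and neural crest (3 of 3), retina and eye (3 of 3), astroglia (4 of 4), and microglia and endothelium (4 of 4). These last 4 lists held 14, 10, 9 and 10 genes, so most of their members were not tested. The retina list turned to 0.71 outside the choroid plexus or hem-like cluster, and the unfolded protein list to 0.0224 without estradiol 2. The estrogen response list was lower, 11 of 13 genes (median -0.38, adjusted p = 3.7e-05). In principal components estradiol 2 stood apart from the other libraries (80.9 on the first, against -24.7 to -6.28). Without estradiol 2, intermediate progenitor genes lay at 0.44 (adjusted p = 5.7e-04), excitatory cortical neuron genes at 0.12 and pan-neuronal genes at 0.16 (0.326 for both), and G2 and M phase at -0.30; outside the choroid plexus or hem-like cluster G2 and M phase lay at -0.13. PPP1R17, a phosphatase inhibitor gene of intermediate progenitors and neurons, had 5.10 and 5.30 CPM in control and 25.2 and 48.0 in estradiol (log2 2.75, SE 0.65, adjusted p = 0.267; DESeq2 adjusted p = 1.4e-04). COL21A1 was at 0 in estradiol (DESeq2 adjusted p = 0.0309), and NEUROD6 (1.36, SE 0.57) and TBR1 (0.93, SE 0.44) did not pass (adjusted p = 0.999). EdgeR called 0 genes with 586 at an unadjusted p under 0.05, and DESeq2 called 3; without estradiol 1, edgeR called 820.

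Within classes, 6 genes were lower in the dividing-like cells of estradiol than in those of control. Without estradiol 2 the calls of PCP4, SERPINF1, TRPM3 and PLS3 were lost, as were those of the last 3 without control 2 and that of PCP4 without control 1. With 1 library left out the number of genes called ran from 15 to 141. PCP4, which binds calmodulin, had 62.1 and 39.1 CPM in control and 1 UMI in each estradiol library (log2 -4.65, SE 0.99, adjusted p = 0.0143). SERPINF1 had 34.9 and 67.0 CPM in control and 1 UMI in each estradiol library (-4.55, SE 1.02, adjusted p = 0.0180), and the actin-bundling gene PLS3 had 51.4 and 125 CPM against 26.9 and 6.89 (-2.80, SE 0.68, adjusted p = 0.0414). HTR2C (74.7 and 140 CPM in control, adjusted p = 0.0143), TRPM3 (34.9 and 136, adjusted p = 0.0180) and TTR (8562 and 4036, adjusted p = 0.0414) were at 0 in estradiol 2 and had 1, 1 and 75 UMIs in estradiol 1. HTR2C, TTR, SERPINF1 and TRPM3 were also among the leading genes of the choroid plexus or hem-like cluster, and PCP4 led an unnamed one, and the choroid plexus or hem-like share was 12.6% of control and 1.19% of estradiol cells. The class joined 2 clusters with medians of 7938.5 and 976 UMIs per cell, which held 95 and 58 cells of control 1, 34 and 121 of control 2, 12 and 147 of estradiol 1, and 75 and 78 of estradiol 2. The mix thus differed between libraries of the same group as well. DESeq2 called none of the 6; with the library number as a replicate block PCP4 (adjusted p = 0.0422) and TTR (9.1e-04) passed. In radial glia-like cells MGST1 (2.14, SE 0.51), ID1, a target of BMP signalling (-2.61, SE 0.62), DHRS3 (1.99, SE 0.48) and ADAMTS18 (1.82, SE 0.44) had an adjusted p of 0.105. In neuron-like cells PPP1R17 gave 2.05 (SE 0.46, adjusted p = 0.0521), NTS -3.09 (SE 0.74, adjusted p = 0.127) and RSPO3 -2.46 (SE 0.61, adjusted p = 0.146).

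Between DHT and estradiol, at the unequal doses above, 1 gene passed within a class. In excitatory neuron-like cells PPP1R17 (chromosome 7, 31686715 to 31708455) had 9.70 and 9.47 CPM in DHT, from 2 and 6 UMIs, and 83.7 and 112 CPM in estradiol, from 32 and 143 UMIs; control neurons had 29.3 and 19.3. The log2 fold change of DHT against estradiol was -3.37 (SE 0.67, adjusted p = 0.00345 by edgeR and 0.0279 by DESeq2; 0.0157 with the library number as a replicate block). Without DHT 2 the adjusted p was 0.147, and the number of genes called within classes ran from 2 to 207 with 1 library left out. The class joined clusters with medians of 4047 and 1192 UMIs per cell, which held 26 and 49 cells of DHT 1, 113 and 122 of DHT 2, 55 and 95 of estradiol 1, and 205 and 70 of estradiol 2. These clusters also had 9 and 6 intermediate progenitor markers raised, beside 11 and 8 of excitatory neurons. A different share of progenitors within the class is thus not told apart from a change within neurons. PPP1R17 gave -2.55 (SE 0.64) in whole libraries without passing in edgeR (adjusted p = 0.842). SPHKAP, at 0 in DHT neurons (adjusted p = 0.0862), EMC10, GRASP (2.62, SE 0.70) and CDKN1A (1.87, SE 0.51) followed; in radial glia-like cells ZIC1 gave 3.92 (SE 0.97, adjusted p = 0.577) and GJA1 2.40 (SE 0.68).

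**Figure D3:**
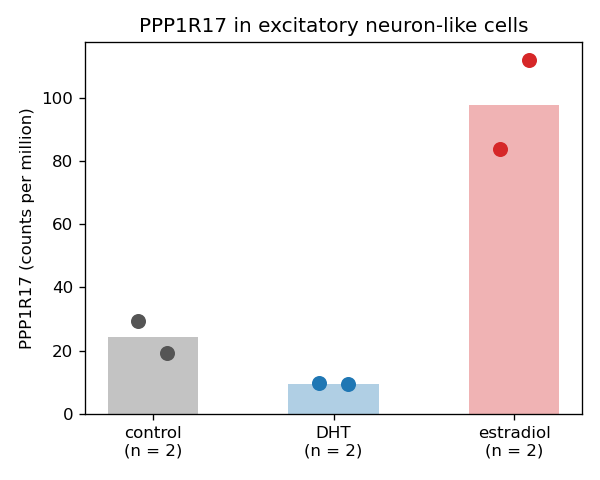
PPP1R17 in excitatory neuron-like cells, in CPM (vertical axis), by treatment; bars are means of 2 libraries and points are the libraries. DHT libraries lie at 9.70 and 9.47, control at 29.3 and 19.3, and estradiol at 83.7 and 112. The class also carries intermediate progenitor markers.

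As groups in whole libraries, camera called 14 lists between DHT and estradiol, and none passed with an estimated correlation (smallest adjusted p = 0.439). Genes of choroid plexus (11 of 11) and hem (9 of 10, median 1.16) were higher in DHT than in estradiol. So were the estrogen response (10 of 13, median 0.50) and unfolded protein lists (16 of 18, median 0.28). The same held for the few tested genes of mesenchyme and neural crest (3 of 3), midbrain and hindbrain (4 of 4) and astroglia (4 of 4). It also held for microglia and endothelium (4 of 4) and inhibitory neurons (4 of 5). Excitatory cortical neuron genes (13 of 18 below 0, median -0.70, adjusted p = 1.1e-05), intermediate progenitor genes (10 of 15, -0.38, 1.8e-05), pan-neuronal genes (11 of 14, -0.47, 0.0024), S phase (17 of 20, -0.36, 0.00108) and G2 and M phase (22 of 22, -0.46, 1.1e-05) were lower. Without estradiol 2, excitatory cortical neuron genes lay at -0.11 (adjusted p = 0.253), pan-neuronal genes at 0.04, G2 and M phase at 0.12, unfolded protein genes at -0.02 and microglia and endothelium at -0.0682. With the library number as a replicate block camera called 15 lists, the added one being retina and eye (3 of 3 above 0, adjusted p = 0.118 without and 0.0229 with the block). The share of choroid plexus or hem-like cells moved with them, 4.61% in DHT and 1.19% in estradiol. EdgeR called 0 genes in whole libraries, with 287 at an unadjusted p under 0.05, and DESeq2 called 1; without estradiol 1, edgeR called 646.

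Genes of steroid action and histone deacetylation were read by class over all 6 single-cell libraries, a comparison chosen after the data were seen. SRD5A1 had 11.8 ± 1.3 CPM in radial glia-like cells and 17.5 ± 1.6 in excitatory neuron-like cells (SD, n = 6), and HDAC2 had 193 ± 20.0 and 322 ± 36.9, both lower in radial glia-like cells in 6 of 6 libraries. An exact two-sided sign-flip permutation test gave p = 0.0313 for each of these, the smallest that 6 libraries allow, and an adjusted p of 0.0625 over 6 genes. HDAC3 (61.6 ± 13.2 against 43.0 ± 16.9 CPM) was higher in radial glia-like cells in 5 of 6 libraries (adjusted p = 0.075), and MTOR did not differ detectably (18.4 against 18.2 CPM; exact p = 0.906).

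**Figure D4:**
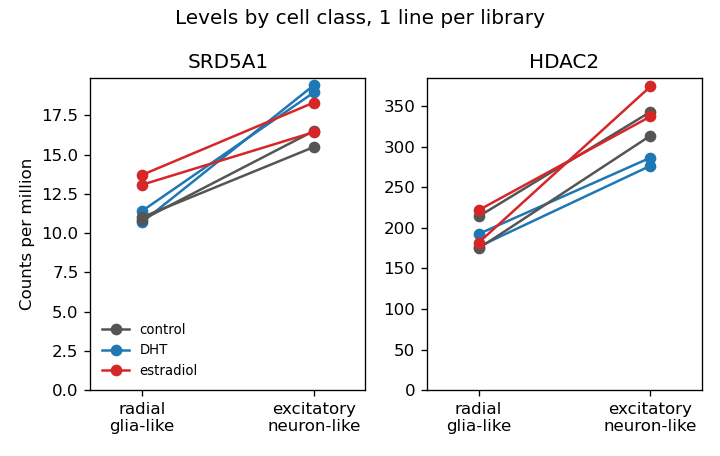
CPM of SRD5A1 and HDAC2 (vertical axis) in radial glia-like and excitatory neuron-like cells; each line is 1 of 6 libraries. SRD5A1 averages 11.8 in radial glia-like and 17.5 in neuron-like cells and HDAC2 193 and 322; both lie higher in neuron-like cells in 6 of 6 libraries.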

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

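The cell filter on a mitochondrial share of at least 0.5%, the demand for a count in every library, the removal of choroid plexus or hem-like cells and the crossed block were chosen after seeing the data; the other settings were fixed before. Direction and side of the threshold held in 819 of 842 comparisons of named bulk genes under other settings and in 895 of 922 with 1 library left out; for named single-cell genes it was 1293 of 1388 and 709 of 799. For called lists it was 60 of 66 and 59 of 77 in bulk, and 227 of 249 and 90 of 128 in single cells. A sign change of a value that passed under neither setting is not counted as a reversal. Class shares moved by less than 1 pooled SD of the libraries in 73 of 84 settings; with 2 libraries per group, leaving 1 out cannot move them further than that, so it shows no stability. At camera's preset correlation the mitochondrially encoded list stayed called in its 4 bulk comparisons under all these settings and left-out libraries; with an estimated correlation it was called in none (adjusted p 0.233 to 0.828). The cause was not tested for any change below. Where leaving out a library left an arm of 1, that library is assumed to vary like the other groups. The unknown read depth limits the bulk zeros, and the UMI totals limit single-cell genes of few counts.

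With a pseudocount of 0.1 TPM, limma called 1 gene in DHT against control and in DHT against testosterone, and 0 in estradiol against control, DHT against estradiol, testosterone against estradiol, androgens against control and androgens against estradiol; camera called 1 list for testosterone against control and 3 for DHT against testosterone. With no filter it called 1 gene for testosterone against control, 11 for estradiol against control, 8 for DHT against estradiol, 7 for testosterone against estradiol and 8 for androgens against estradiol, and 11 lists for DHT against control, 2 for estradiol against control, 12 for DHT against testosterone, 6 for androgens against control and 3 for androgens against estradiol. With a mean of at least 5 TPM, and with the replicate block, 0 genes were called in the 6 bulk comparisons that had any; the mean filter gave a shared-response r of 0.398 and turned 1 median (bulk list: cholesterol synthesis DHT versus control) to -0.0017 (adjusted p = 0.0589), and the block called 5 lists for DHT against testosterone and 6 for androgens against estradiol. Median-ratio rescaling called 1 gene for testosterone against control and 3 lists for DHT against testosterone. With only the groups compared in the fit, 1 gene was called for DHT against control, 5 for estradiol against control, 0 for the other 4 comparisons that had any, and 4 lists for DHT against testosterone.

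In single cells, with no filter on low counts edgeR called 23, 270 and 86 genes in whole libraries (DHT against control, estradiol against control, DHT against estradiol), 65, 79 and 45 within classes, and 7 lists for DHT against control. DESeq2 called 3 genes for estradiol against control and 1 for DHT against estradiol in whole libraries, 0 within classes for estradiol against control, and 7 lists for DHT against control. Cells with a mitochondrial share of at least 0.5% gave 7 lists for DHT against control, 1 gene for estradiol against control, 3 within classes for DHT against estradiol, and a difference of -0.979 points (single-cell class shares DHT versus control: dividing-like). Cells with at least 1000 genes gave 1 gene for estradiol against control, 4 within classes for DHT against estradiol, and a radial glia-like difference of 4.06 points for DHT against estradiol. Genes with a count in every library gave 9 lists each for estradiol against control and DHT against estradiol, and 2 genes within classes for the latter. Leiden resolution 1.5 gave a dividing-like difference of -1.70 points for DHT against control. The replicate block by library number called 2 genes within classes for estradiol against control; within numbers 1 and 2 the neuron-like difference was -0.940 and 4.85 points for DHT against control and -1.96 and 19.5 for estradiol against control, and the radial glia-like one -12.8 and 5.83 for estradiol against control and 3.78 and -6.93 for DHT against estradiol. The crossed block, tried because the differences between numbers 1 and 2 in control and estradiol correlated at -0.06 over tested genes (against 0.204 in control and DHT), called 52 genes within classes for estradiol against control. Outside choroid plexus or hem-like clusters, the retina list of estradiol against control turned to 0.71 and G2 and M phase to -0.13.

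With 1 bulk library left out, the count for DHT against control (2) ran from 0 to 20: 0 without control 1706, 1805 or 0802, 1 without DHT 1706 or 1805 and 20 without DHT 0802. Its lists (4) ran from 2 (without DHT 1805) to 10 (DHT 0802), with 8 without control 1706 and 7 without control 0802. Testosterone against control (0) ran from 0 to 1 (testosterone 1706), its lists (2) from 1 (testosterone 1706) to 10 (testosterone 0802), with 4 without control 1706 and 5 without control 0802. Estradiol against control (1) ran from 0 (any control, or estradiol 1805) to 1, its lists (0) from 0 to 3 (control 1706), with 1 without estradiol 1805 and 2 without control 0802. DHT against testosterone (0) ran from 0 to 20 (DHT 0802), with 1 without DHT 1706, testosterone 1706 or DHT 1805; its lists (1) ran from 0 (testosterone 1805 or 0802) to 7 (testosterone 1706), with 3 without DHT 1706, 2 without DHT 1805 and 6 without DHT 0802. DHT against estradiol (1) ran from 0 (DHT 1706 or estradiol 1805) to 9 (DHT 0802), and testosterone against estradiol (1) from 0 (estradiol 1805, testosterone 1805 or 0802) to 1. Androgens against control (1) ran from 0 (DHT 1706, testosterone 1706 or 1805, control 1805 or 0802) to 2 (control 1706, DHT 1805 or 0802, testosterone 0802), its lists (3) from 2 (testosterone 1706 or 1805, DHT 1805) to 12 (DHT 0802), with 5 without control 1706, control 0802 or testosterone 0802. Androgens against estradiol (1) ran from 0 (estradiol 1805) to 3 (estradiol 1706), its lists (1) from 1 to 4 (estradiol 1706, DHT 0802 or testosterone 0802). The shared-response r ran from 0.446 without 1706 to 0.508 without 1805 or 0802. Calls were also lost for a list of testosterone against control (bulk list: steroid receptors and steroid enzymes testosterone versus control) without testosterone 1706 (adjusted p = 0.0969), control 1805 (0.107) or control 0802 (0.0536), the hem list of DHT against testosterone without DHT 1706 (0.391), testosterone 1805 (0.175) or testosterone 0802 (0.126), and S phase of androgens against control without control 1805 (0.134). The call of bulk list: cholesterol synthesis DHT versus control was lost without DHT 1706 (0.164), control 1805 (0.167) or DHT 1805 (0.0867). That of bulk list: cholesterol synthesis androgens versus control was lost without DHT 1706 (0.0639), testosterone 1706 (0.0823), control 1805 (0.2999), DHT 1805 (0.0806) or testosterone 1805 (0.0689).

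With 1 single-cell library left out, genes within classes ran from 9 (control 1) to 18 (control 2) for DHT against control (0), with 10 without DHT 1 and 11 without DHT 2; from 15 (control 2) to 141 (estradiol 1) for estradiol against control (6), with 22 without control 1 and 93 without estradiol 2; and from 2 (DHT 1) to 207 (estradiol 1) for DHT against estradiol (1), with 18 without DHT 2 and 12 without estradiol 2. Whole-library counts stayed at 0 for DHT against control, and ran from 0 to 820 (estradiol 1) for estradiol against control and from 0 to 646 (estradiol 1) for DHT against estradiol, with 2 in both without estradiol 2. Lists ran from 4 (DHT 2) to 12 (control 2) for DHT against control, with 9 without DHT 1, from 5 (estradiol 2) to 18 (estradiol 1) for estradiol against control, and from 4 (estradiol 2) to 18 (estradiol 1) for DHT against estradiol. Medians turned for estradiol against control in G2 and M phase (-0.30 without estradiol 2 to 0.74 without estradiol 1) and unfolded protein genes (-0.81 without estradiol 1 to 0.0224 without estradiol 2). For DHT against estradiol they turned in pan-neuronal genes (-0.89 without DHT 2 to 0.0367 without estradiol 2), microglia and endothelium (-0.0682 without estradiol 2 to 8.25 without estradiol 1), G2 and M phase (-0.82 without estradiol 1 to 0.12 without estradiol 2) and unfolded protein genes (-0.0216 without estradiol 2 to 0.73 without estradiol 1), and for TTR in radial glia-like cells (-1.17 without estradiol 2 to 11.47 without estradiol 1). TTR was at 0 in the radial glia-like cells of estradiol 2, so that last value has no meaning as a fold; AIF1, CLDN5, CSF1R and KDR of the microglia and endothelium list were at 0 in estradiol 2 too, and the same holds for 8.25. Of the 6 genes lower in dividing-like cells of estradiol, PCP4 was lost without control 1 (adjusted p = 0.0553) and estradiol 2 (0.110), SERPINF1 without control 2 (0.615) and estradiol 2 (0.138), TRPM3 without control 2 (0.228) and estradiol 2 (0.105), and PLS3 without control 2 (0.708) and estradiol 2 (0.233).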

Other observations

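The tests below of library shares, genes at 0 and splits of the libraries were chosen after the results were seen, except that of nuclear respiratory chain genes.

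Choroid plexus transcripts were present outside the choroid plexus or hem-like cells. Over 8 choroid plexus markers, radial glia-like cells held 1971 CPM in control 1, 303 in control 2, 316 in DHT 1, 160 in DHT 2, 505 in estradiol 1 and 7.47 in estradiol 2, from 12 UMIs. Dividing-like cells held 8707 CPM in control 1 and 9.18 in estradiol 2. TTR, which codes for the thyroid hormone carrier of the cerebrospinal fluid, made up most of this: 1945 CPM in the radial glia-like cells of control 1 and 0 in those of estradiol 2. In bulk, batch 0802 differed from the others in the choroid plexus: TTR had 98.9 TPM in control, 198 in DHT and 162 in testosterone there, against 192, 64.7 and 132 in batch 1805.

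Low-mitochondria cells had less RNA than the rest. In control 1 those with a mitochondrial share under 0.5% had a median of 1004.5 UMIs, against 5454 for the others, and in estradiol 2 the medians were 1387.5 and 3824. MALAT1, a nuclear RNA, was detected in 54.1% of the low-mitochondria cells of control 1 and in 91.0% of its other cells, without matching for UMIs. Its median share of the UMIs was 0.050% and 7.23% in these cells. In the low-mitochondria cells of control 2, DHT 1, DHT 2 and estradiol 1 that median was 0%, and in those of estradiol 2 it was 0.045%. In the other cells of these libraries it ran from 2.77% to 9.12%. Ribosomal protein genes made up a median of 26.1% and 19.9% of the UMIs of these low-mitochondria and other cells of control 1. Histone deacetylase genes, which the question of the series touches, lay below 0 in 16 of 20 between bulk DHT and control (median -0.27, adjusted p = 0.323), hypoxia and glycolysis genes in 16 of 20 (-0.23, 0.221) and Wnt pathway genes in 8 of 10 (-0.36, 0.107), while mTOR genes split 10 above and 12 below 0 (0.473). Notch pathway genes had a median of -0.08 (0.779) and 3 muscle genes one of -0.25 (0.748), and none of these lists was called; all genes together had a median of -0.0847 there.

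The first pattern is the lower share of mitochondrially encoded transcripts in both androgen groups. Every batch held a control, a DHT and a testosterone library, so a shift common to a batch cancels from this comparison by design. The mean of the within-batch log2 differences, -0.66 (SD 0.47 over 3 batches), therefore restates the pattern and is no separate test of such a shift. The scaling of the deposited values is argued against by a median of -0.62 for the 13 genes after rescaling. Fewer choroid plexus and hem cells remain a candidate explanation in batches 1706 and 1805, where 4 of 4 androgen libraries had these markers below their control. The sizes did not follow each other, though (DHT 1706 -0.90 with a mitochondrial change of -0.07, testosterone 1805 -0.36 with -0.90). The explanation is no candidate in batch 0802, where the lower of the 2 medians was 0.66 above control. The division by batch was made after the values were seen. This explanation also needs these cells to be richer in mitochondrial transcripts than the rest, which was not tested. In the single-cell libraries their cluster had a median mitochondrial share of 3.17%, and the medians of the other clusters ran from 0% to 4.42%, which does not decide it. Under a lower mitochondrial content of the cells, the nuclear genes of the respiratory chain were predicted to fall too, and they did not. The 93 genes, picked by name prefix and including assembly factors such as NDUFAF1, had a median of 0.0674 (SD 0.25), 38 below and 55 above 0. This argues against a joint fall of these nuclear transcripts. Mitochondrial content itself was not measured, and transcripts of nuclear genes cannot settle it. An effect of androgens on mitochondrial transcripts themselves was not tested.

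The second pattern is the lack of choroid plexus or hem-like cells in estradiol 2. The lack was not particular to them: the unnamed cluster of 1300 cells had 1 cell in estradiol 2, against 138 to 419 in the other libraries. That cluster had a median of 984.5 UMIs per cell and a median mitochondrial share of 0%. Whether it is a cell type or cells of low quality was not tested. The points below concern the choroid plexus or hem-like cells only. A lower depth of estradiol 2 is argued against by its median of 3164 UMIs per cell, above that of 4 of the other libraries. Removal of such cells after capture is argued against by the 7.47 CPM of their markers in its radial glia-like cells, against 160 to 1971 in the other libraries: RNA set free by captured cells would be left behind in the rest. Whether estradiol itself lowers these cells cannot be told apart from variation between organoids: the bulk estradiol libraries had medians of -0.0224 in 1706 and -0.35 in 1805 for the same markers, and estradiol 1 held 28 such cells.

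The third pattern is that the bulk genes called were listed at 0 in every library outside 1 group. Of the 165 sets of 3 libraries, 34 had at least 1 gene of this kind (20.6%), so listing at 0 sets 3 libraries apart whatever their treatment. Pairs of libraries, the size of the estradiol group that ENSG00000265630 sets apart, were not counted. Of the 38 genes that set any 3 libraries apart, 37 were pseudogenes (97.4%, exact 95% interval 86.2% to 99.9%), against 12.7% of all genes tested. The 38 genes were picked for being listed at 0 in every other library, and the tested genes were not matched to them for level. This contrast therefore cannot decide whether reads were shared between near-identical copies. A gene switched on by DHT stays open for SPTLC1P1: 4 sets of 3 libraries had more genes of this kind than the DHT set.

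Other splits of the same libraries were counted for the bulk results. The splits of DHT and control, of testosterone and control, and of DHT and testosterone number 10 each, too few for a share under 0.05: the real counts were 2, 0 and 0 genes, as large in 1, 10 and 10 splits, and the highest of the others were 1, 2 and 1. For androgens and control, 23 of 84 splits called at least the real 1 gene, so chance is not excluded, and 1 split called 63, which points to a structure of the samples; what sets that split apart was not tested. The splits were drawn without regard to batch, so some of them set batches against each other. With the batch as a replicate block the real split called 0.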
